A study of Homo sapiens with 32 samples.

How the data were processed

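Gene expression was measured by RNA sequencing of total RNA from MM.1S, a human multiple myeloma cell line. Per the labels' protocols, cells were pulsed for 1 h with vehicle (DMSO) or with the proteasome inhibitor carfilzomib (Cfz), and were then kept for 12 h in medium with DMSO or with 10 µM all-trans retinoic acid (ATRA). The carfilzomib dose is not given in the sources used here. RNA was extracted with an RNeasy kit and libraries followed standard Illumina protocols, per the labels' protocols. The 32 samples are 4 sequencing lanes of each of 8 libraries, per the labels: 3 libraries with DMSO, 3 with ATRA, 1 with Cfz and 1 with ATRA after Cfz (ATRA+Cfz).

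Per the submitters' processing notes, reads were processed with fastp 0.20.0, kallisto 0.46.2 and DESeq2 (no version stated). The genome build and the transcript annotation are not given in the sources used here, nor is the strand setting, so genes that overlap on opposite strands may share reads in these values. The authors deposited FPM values, a CPM unit in which fragments are scaled to a fixed total, for each lane separately. Each of the 32 columns summed to 1000000 over 24249 distinct gene IDs. The table holds 24402 lines because 143 gene IDs stand on more than 1 line, with the same value in each lane, and each ID was used once. No gene had fewer than 10 reads in total. Because the values are steps of 1 read, whole reads could be recovered for 100% of the values within 0.01 read. Symbols came from the table for 17006 gene IDs, from GENCODE release 29 for 6482 and from a table of gene names for 754, and 7 IDs stayed without a symbol.

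Recovered depth was 17155331, 16567946 and 14945279 reads for DMSO 1 to 3, 15876106, 14381173 and 15699575 reads for ATRA 1 to 3, 15245884 reads for Cfz and 14136937 reads for ATRA+Cfz, with 3497264 to 4321393 reads per lane. A floor of 3 reads per library corresponds to 0.175 to 0.212 FPM. Intervals and floors cover counting error only. Lanes of 1 library differed little more than sampling noise, with a chi-square per degree of freedom of 1.183 to 1.241, so the 4 lanes were averaged and each library was counted once. The same measure was 1.872 for DMSO 1 against DMSO 2, 11.7 and 12.379 for DMSO 3 against DMSO 1 and DMSO 2, and 1.838 to 3.093 between ATRA libraries. For 533 of the 15827 genes tested (3.4%), the lanes of at least 1 library differed by more than sampling noise. Of the 148 genes looked up for the text, 15 were among them. Those named here are marked as uncertain, also in comparisons that do not hold the library with differing lanes.

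Tests were made with limma 3.58.1 in R 4.3.3, with an intensity trend, on log2(FPM + 0.5) per library. Fold changes are therefore on the log2(FPM + 0.5) scale, which understates the change of low genes. Genes were kept where the mean of the 4 group means was at least 0.5 FPM. All 8 libraries entered 1 fit with 4 residual and 7.2 prior degrees of freedom, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. The spread came from the DMSO and ATRA libraries, so the lone Cfz and ATRA+Cfz libraries were assumed to vary like them and their differences have no replicate check. The labels do not say whether libraries came from separate cultures, so the p-values measure only the spread between libraries, which may be technical. Comparisons were ATRA, Cfz and ATRA+Cfz against DMSO, ATRA+Cfz against Cfz and against ATRA, and the interaction, which is the ATRA effect after Cfz minus the ATRA effect without it.

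The groups, tests, gene lists, rule for named genes and most alternative settings were fixed before the data were examined. The rule named, among called genes with a symbol and at least 2 FPM in the higher group whose libraries did not overlap, the 12 largest rises and 12 largest falls for each treatment against DMSO, and the 6 largest in each direction for the other comparisons. It also named 2 to 6 members per list with the smallest p, and 13 genes tied to the treatments (among them RARA, RARB, RARG, CYP26A1, DHRS3, CD38, PSMB5, OAS1, OAS2, OAS3, OASL and IRF1). Some genes that the rule named are not reported here, and counts over named genes include them. The 28 lists were retinoid response, OAS pathway, type I interferon-stimulated genes, interferon signalling and nucleic acid sensing, MHC class I presentation, immunoproteasome, constitutive proteasome, heat shock, ER unfolded protein response, ATF4 integrated stress response, NRF2 oxidative stress, metallothionein, ubiquitin and autophagy, BCL2 family and death receptors, p53 target, NF-kB target, plasma cell identity, MYC and nucleolar, DNA replication (S phase), mitosis (G2/M), cholesterol synthesis, ribosomal protein, mitochondrially encoded, replication-dependent histone, and 4 lists of markers of T and NK, myeloid, stromal and epithelial cells. Some genes stand on more than 1 list. Counts cover tested members only, such as 12 of 22 listed retinoid genes and 42 of 52 listed interferon-stimulated genes. Lists with at least 5 tested members, 23 in all, were tested for ATRA against DMSO with camera at a preset inter-gene correlation of 0.01 and again with an estimated correlation. For comparisons with a lone library, the list's median was placed among 10000 random lists of the same size matched on mean expression in 50 bins, as a description of these libraries.

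The pipeline was tested on simulated reads for the 15827 genes with known fold changes. Of 67 genes changed 2-fold, limma called 74.6% for ATRA against DMSO, 71.6% for Cfz against DMSO, 76.1% for ATRA+Cfz against DMSO, 68.7% for ATRA+Cfz against Cfz, 73.1% for ATRA+Cfz against ATRA and 67.2% for the interaction. Of 67 genes changed 1.5-fold, it called 68.7% for ATRA against DMSO, 46.3% for Cfz against DMSO and 40.3% for the interaction. Unchanged genes called numbered 8 for ATRA against DMSO, 9 for Cfz against DMSO and 10 for the interaction. These counts hold for the simulated reads only. In the real data a lone control library gave far more calls against its own group, as reported below. The simulated counts therefore cannot be read as an error rate for comparisons that rest on a lone library.

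The alternative settings were pseudocounts of 0.1 and 2, no filter on low values, a minimum of 5 FPM, median-ratio scaling, robust empirical Bayes, lanes as samples and lane 1 alone. Each DMSO or ATRA library was also left out in turn, while the lone Cfz and ATRA+Cfz libraries were always kept. Further settings were a replicate block, the DMSO and ATRA libraries alone, an added 2-fold minimum, edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 (Wald test) on the recovered whole reads. A correction of each library for its trend on GC content and transcript length, from GENCODE release 29 and available for 15557 genes (98.3% of those tested), was added after the data were seen. So were the counts of list members under other settings, the list tests under settings other than an estimated correlation and the replicate block, and the agreement of effects with robust empirical Bayes, lanes as samples, edgeR and DESeq2. Tables were handled in python 3.11.15 with pandas 2.3.3 and drawn with matplotlib 3.10.9.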

Results

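Total RNA of MM.1S myeloma cells was sequenced after 4 treatments: DMSO (n = 3 libraries), ATRA (n = 3), a carfilzomib pulse (Cfz, n = 1) and a carfilzomib pulse followed by ATRA (ATRA+Cfz, n = 1). ATRA is a vitamin A derivative that activates nuclear retinoic acid receptors, and carfilzomib blocks the chymotrypsin-like site of the proteasome, carried by the subunit PSMB5. Depth was 14136937 to 17155331 reads per library, and 15827 genes were tested. The 10 most abundant genes held 6.35% to 7.35% of reads. The first principal component (59.6% of the variance) set the ATRA and ATRA+Cfz libraries apart from the DMSO and Cfz libraries, and the second (18.9%) set both libraries with carfilzomib apart from the other 6.

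One control stood apart from the others. DMSO 3 differed from DMSO 1 and DMSO 2 by a chi-square per degree of freedom of 11.7 and 12.4, against 1.87 between DMSO 1 and DMSO 2. Mitochondrially encoded genes took 5.85% of its reads (95% Wilson interval 5.84% to 5.87%), against 4.12% and 4.09% in DMSO 1 and DMSO 2, 3.67% to 3.89% in the ATRA libraries, 5.43% with Cfz and 5.72% with ATRA+Cfz. Markers of other cell types were low: S100A9, a myeloid marker, reached 1.01 FPM and the T cell marker CD3E 1.54 FPM in any library. The stromal marker COL6A3 lay between 10.6 and 23.5 FPM in all 8 libraries while COL1A1 stayed at or below 0.232 FPM. Of the 8 metallothionein genes listed, 2 were in the table and 0 were tested, with at most 0.85 FPM.

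**Figure D1:**
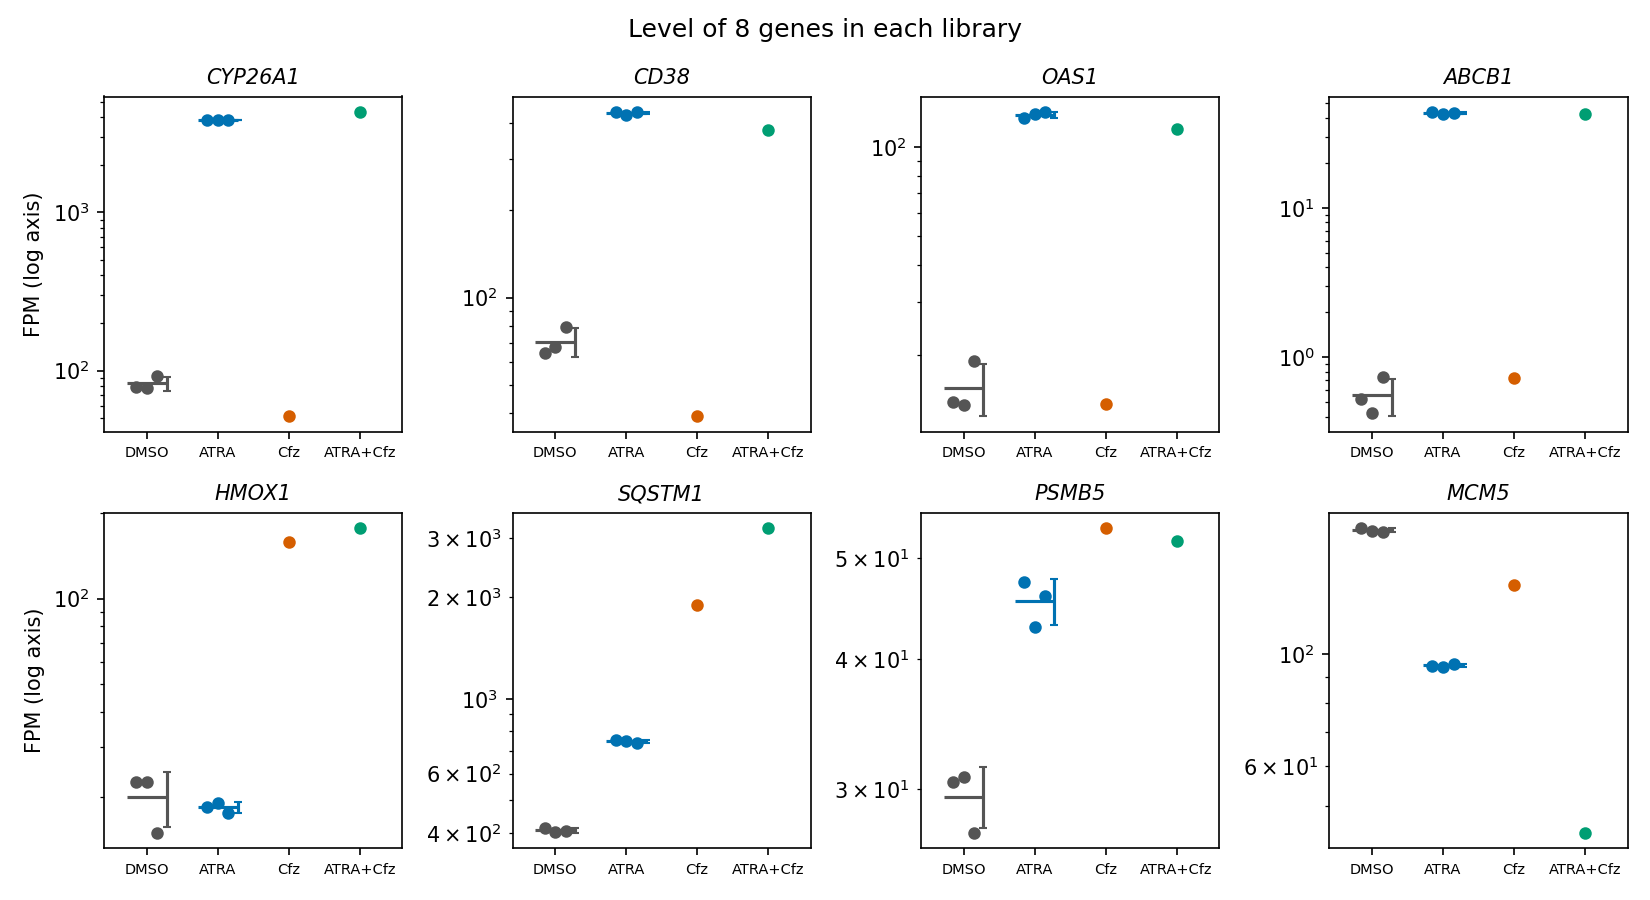
FPM of 8 genes (log axes that do not start at 0) in each library; points are libraries, horizontal lines group means and brackets the SD of the 3 DMSO and 3 ATRA libraries, and Cfz and ATRA+Cfz have 1 library each. CYP26A1 rose from 83.2 FPM with DMSO to 3810 FPM with ATRA, and HMOX1 rose from 20.1 FPM with DMSO to 159 FPM with Cfz.

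The first question was which transcripts changed over 12 h of ATRA. CYP26A1, which encodes the cytochrome P450 that degrades retinoic acid, rose from 83.2 ± 8.5 FPM with DMSO to 3810 ± 7.1 FPM with ATRA (SD, n = 3 each, log2 fold change 5.52 ± 0.06 SE, limma, Benjamini-Hochberg adjusted p = 8.6e-14). HAPLN3, a hyaluronan and proteoglycan link protein, rose from 1.21 ± 0.23 to 96.5 ± 4.5 FPM (5.84 ± 0.1 SE), and MFGE8, a secreted phosphatidylserine-binding protein, from 21.4 ± 1.6 to 1010 ± 6.5 FPM (5.53 ± 0.05 SE). ABCB1, the drug efflux pump P-glycoprotein, rose from 0.56 ± 0.16 to 43.1 ± 0.72 FPM (5.37 ± 0.13 SE, limma, Benjamini-Hochberg adjusted p = 8.2e-11). The integrin subunit ITGB8 fell from 61.7 ± 13 to 5.56 ± 0.68 FPM (-3.34 ± 0.14 SE), and ID2, an inhibitor of basic helix-loop-helix factors, from 28 ± 0.26 to 3.28 ± 0.39 FPM (-2.92 ± 0.1 SE). The rule for genes named by the size of their change required the 3 ATRA libraries to lie on 1 side of the 3 DMSO libraries. That they do so here is therefore no further finding.

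The other largest rises were SV2B, a synaptic vesicle glycoprotein (log2 fold change 4.59), IRAK2, a kinase of Toll-like receptor signalling (4.32), the receptor CALCRL (4.3), CPNE5 (4.18), the potassium channel KCNH4 (4.13), the interferon-inducible GTPase GBP4 (4), the acyl-CoA synthetase ACSM5 (4) and the ubiquitin ligase TRIM31 (3.93). The lanes of CPNE5 differed in ATRA 1, at 114 to 146 FPM, against 3.7 to 10.5 FPM over the DMSO lanes. The size of its rise is therefore uncertain, but not its direction. The other largest falls were SEMA5A (-2.7), the chemokine receptors CX3CR1 (-2.54) and CXCR3 (-2.52), CBLN2 (-2.52), RASAL2 (-2.48), ADAMTS15 (-2.48), NEURL1 (-2.44), the heparan sulfate proteoglycan SDC2 (-2.43), the MYC family member MYCL (-2.3) and the CXCR3 ligand CXCL10, which fell from 19 ± 7 to 3.43 ± 0.62 FPM (-2.24 ± 0.24 SE).

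Among 12 tested genes of the retinoid response, 9 rose, 1 fell and 2 were not called (10 and 1 adjusted over the list alone, median 1.07). CD38, a surface ectoenzyme that antibodies target in myeloma, rose from 70.6 ± 7.8 to 431 ± 4.5 FPM (2.61 ± 0.06 SE). ASB2 (2.69), an ankyrin-repeat ubiquitin ligase subunit, PLAAT4 (2.58), a phospholipase also named RARRES3, and the receptors RARA (0.73) and RARB (0.95) rose too. RARB was low, at 0.176 to 0.403 FPM with DMSO and 0.895 to 1.32 FPM with ATRA. Its DMSO values lie near the floor of 3 reads, and its fold change depends on the 0.5 FPM added before the logarithm. RARG was at 8.5 ± 0.74 and 10.3 ± 0.85 FPM (0.26 ± 0.1 SE, limma, Benjamini-Hochberg adjusted p = 6.0e-02). DHRS3, a retinaldehyde reductase, was under the expression minimum, at 0.0664 to 0.122 FPM with DMSO and 0.572 to 0.821 FPM with ATRA. The camera test gave the list as higher (adjusted p = 3.2e-06; adjusted p = 5.1e-02 with an estimated correlation).

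The OAS pathway senses double-stranded RNA. Its list also holds genes that are not OAS genes, among them ABCE1 and PDE12. Of its 6 tested members, 5 rose and 1 fell (5 and 1 adjusted over the list alone, median 0.89). The camera test gave an adjusted p = 4.5e-04, and an adjusted p = 0.24 with an estimated correlation. OAS1 rose from 15.5 ± 3.1 to 128 ± 3.2 FPM (3.02 ± 0.1 SE), OAS3 from 13.5 ± 1.7 to 58.8 ± 0.79 FPM (2.09) and OAS2 from 42.7 ± 1.2 to 121 ± 2.1 FPM (1.49). These 3 related genes lie next to each other. OASL was not tested, at 0.12 to 0.201 FPM with DMSO and 0.252 to 0.382 FPM with ATRA.

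Other interferon genes went both ways. Of 42 type I interferon-stimulated genes, which include the OAS genes, 15 rose, 10 fell and 17 were not called (15 and 11 adjusted over the list alone), with a median of -0.04 against a mean of 0.1 (camera adjusted p = 0.11). Without ATRA 2, 5 fell, and with DESeq2 4 did. UBE2L6, the ISG15-conjugating enzyme, rose from 48.6 ± 2 to 101 ± 3.6 FPM (1.05), and ISG20, an exonuclease, from 31.3 ± 2.2 to 55.8 ± 3.4 FPM (0.82). The antiviral GTPase MX1 fell from 18.5 ± 0.98 to 9.74 ± 0.081 FPM (-0.89). In interferon signalling, 7 of 23 rose and 8 fell (7 and 8 adjusted over the list alone, camera adjusted p = 0.47). IRF1, an interferon-induced transcription factor, rose from 82.8 ± 0.78 to 200 ± 6.4 FPM (1.27), the receptor chain IFNGR1 by 0.76 and the RNA sensor IFIH1 by 0.43. MHC class I presentation had 7 of 12 higher and 3 lower (7 and 3 adjusted over the list alone, camera adjusted p = 0.14), and the immunoproteasome 3 of 5 higher and 0 lower (3 and 0 adjusted over the list alone, camera adjusted p = 0.065).

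Of 33 genes of the constitutive proteasome, 31 rose and 0 fell (32 and 0 adjusted over the list alone, median 0.37). Camera gave adjusted p = 1.4e-16 for the list, and adjusted p = 0.035 with an estimated correlation. PSMB4 rose from 286 ± 4.7 to 424 ± 3.7 FPM (0.57 ± 0.03 SE), PSMB7 from 108 ± 3.6 to 170 ± 1.5 FPM (0.66), the assembly factor POMP by 0.68 and PSMB5 from 29.5 ± 2 to 45.5 ± 2.3 FPM (0.62). All 15 genes of the ubiquitin and autophagy list rose (15 adjusted over the list alone, median 0.39), among them the autophagy receptor SQSTM1 from 407 ± 6.9 to 748 ± 7 FPM (0.88), GABARAPL1 (1.56) and ZFAND5 (0.61). In camera the list had an adjusted p = 2.7e-09, and an adjusted p = 0.14 with an estimated correlation. The ATF4 integrated stress response had 19 of 22 higher and 1 lower (19 and 1 adjusted over the list alone, median 0.47). Tested with camera, the list had an adjusted p = 2.3e-09, and an adjusted p = 0.035 with an estimated correlation. Its largest rise was DDIT4, an mTORC1 inhibitor, from 6.49 ± 0.61 to 76.9 ± 3.2 FPM (3.47 ± 0.07 SE), with the tryptophanyl-tRNA synthetase WARS1 at 0.95 and the phosphatase subunit PPP1R15A at 0.8. In the NRF2 oxidative stress list, 9 of 14 rose and 2 fell (9 and 2 adjusted over the list alone, median 0.35), with the cystine transporter SLC7A11 at 1.43, ME1 at 1.05 and SRXN1 at 0.82. In this list 4 fell without DMSO 3, and 1 without DMSO 2 or ATRA 1. The camera test gave an adjusted p = 9.7e-04, and an adjusted p = 0.24 with an estimated correlation.

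The cell cycle lists fell. All 19 genes of DNA replication fell (19 adjusted over the list alone, median -0.81), with a camera adjusted p = 3.9e-14, and an adjusted p = 0.083 with an estimated correlation. So did all 20 genes of mitosis (20 adjusted over the list alone, median -0.73), with a camera adjusted p = 8.4e-12, and an adjusted p = 0.26 with an estimated correlation. The helicase subunit MCM4 fell from 531 ± 12 to 277 ± 4.5 FPM (-0.94), and UHRF1, which recruits maintenance DNA methylation, from 145 ± 9.3 to 54.8 ± 1.4 FPM (-1.39). The ribonucleotide reductase subunit RRM2 fell from 1210 ± 75 to 552 ± 2.7 FPM (-1.13), the proliferation marker MKI67 from 916 ± 40 to 420 ± 7.5 FPM (-1.12) and TOP2A from 618 ± 44 to 328 ± 5.8 FPM (-0.91). Of 16 p53 targets, 4 rose and 8 fell (4 and 8 adjusted over the list alone, median -0.33, camera adjusted p = 0.22). The cell cycle inhibitor CDKN1A rose from 21.1 ± 0.29 to 56.8 ± 1.5 FPM (1.41) and PLK2 fell from 24.6 ± 4.2 to 5.99 ± 0.59 FPM (-1.94). Ribosomal protein genes rose by a small amount, with 58 of 59 higher and 0 lower (58 and 0 adjusted over the list alone, median 0.28). Examples are RPS19 (0.59) and RPL24 (0.61). Camera gave adjusted p = 2.5e-21 for the list, and adjusted p = 0.14 with an estimated correlation. The MYC and nucleolar list had 10 of 21 higher and 4 lower (10 and 4 adjusted over the list alone, median 0.11). MYC itself rose from 339 ± 0.95 to 672 ± 4 FPM (0.99). In camera the list had an adjusted p = 0.017, and an adjusted p = 0.16 with an estimated correlation.

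Of 19 plasma cell identity genes, 11 rose and 5 fell (12 and 5 adjusted over the list alone, median 0.45). Tested with camera, the list had an adjusted p = 2.3e-03, and an adjusted p = 0.4 with an estimated correlation. XBP1, a transcription factor of secretory cells, rose from 895 ± 9.9 to 2650 ± 11 FPM (1.56), and the surface marker SDC1 (CD138) from 423 ± 27 to 1230 ± 34 FPM (1.54). The transcription factor MAF rose from 894 ± 6.3 to 1720 ± 7.3 FPM (0.94), while the cyclin CCND2 fell from 1640 ± 63 to 1090 ± 3 FPM (-0.59). In the BCL2 family and death receptors, 10 of 19 rose and 4 fell (10 and 4 adjusted over the list alone, median 0.21). The survival gene MCL1 rose from 617 ± 4.3 to 1390 ± 15 FPM (1.17) and the pro-apoptotic BAK1 by 0.91, and the survival gene BCL2L1 fell from 263 ± 7.4 to 141 ± 4.1 FPM (-0.9). The camera test gave an adjusted p = 0.032, and an adjusted p = 0.17 with an estimated correlation. Mitochondrially encoded genes had 8 of 13 lower and 0 higher (11 and 0 adjusted over the list alone, median -0.38). This comparison holds the control of high mitochondrial share, and without it 12 were lower. The number was also 12 without DMSO 2 and with the replicate block and 11 without DMSO 1, but 4 without any one of the ATRA libraries, 5 with median-ratio scaling, 3 with DESeq2 and 1 with robust empirical Bayes. Camera gave adjusted p = 0.035 for the list, and adjusted p = 0.57 with an estimated correlation. MT-ATP6 was at 2510 ± 460 FPM with DMSO and 1810 ± 78 FPM with ATRA (-0.46), a call lost with robust empirical Bayes at the same value.

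The camera test did not call the remaining lists. Heat shock had 7 of 21 higher and 3 lower (7 and 3 adjusted over the list alone, camera adjusted p = 0.21), and 6 lower without DMSO 3. The ER unfolded protein response had 6 of 19 higher and 7 lower (6 and 7 adjusted over the list alone, camera adjusted p = 0.46), and 4 lower without DMSO 1, DMSO 2 or ATRA 2. NF-kB targets had 6 of 14 higher and 5 lower (6 and 5 adjusted over the list alone, camera adjusted p = 0.47). Cholesterol synthesis had 9 of 23 higher and 3 lower (9 and 3 adjusted over the list alone, camera adjusted p = 0.065), and 5 lower without DMSO 3. Its members that rose include the sterol reductase DHCR7 (0.94) and INSIG1 (0.81). Replication-dependent histones had 2 of 6 higher (0 adjusted over the list alone, camera adjusted p = 0.18). The number was 1 without DMSO 3 and with correction for GC content and length, and 0 without DMSO 2 or any one of the ATRA libraries. Of the markers of other cell types, 1 of 2 T and NK cell markers was lower and 1 of 2 myeloid markers higher (the same numbers adjusted over the list alone), and with DESeq2 neither was called. Neither the 2 stromal markers nor the 1 epithelial marker tested were called, while 1 stromal marker was higher without DMSO 1 and 1 lower without DMSO 2. With ATRA, limma called 7704 genes at a Benjamini-Hochberg adjusted p under 0.05, 3368 higher and 4336 lower. That is 48.7% of the genes tested, the share against which the list counts with ATRA are to be read. Of the called genes, 312 were at least 2-fold higher and 473 at least 2-fold lower. The share of calls that were higher was 43.7%, against 49.2% with median-ratio scaling, 48.4% with edgeR, 48.8% with DESeq2 and 51.8% after correction for GC content and length. Of the 13 lists that camera called with the preset correlation, the constitutive proteasome and the ATF4 list were called with an estimated correlation.

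**Figure D2:**
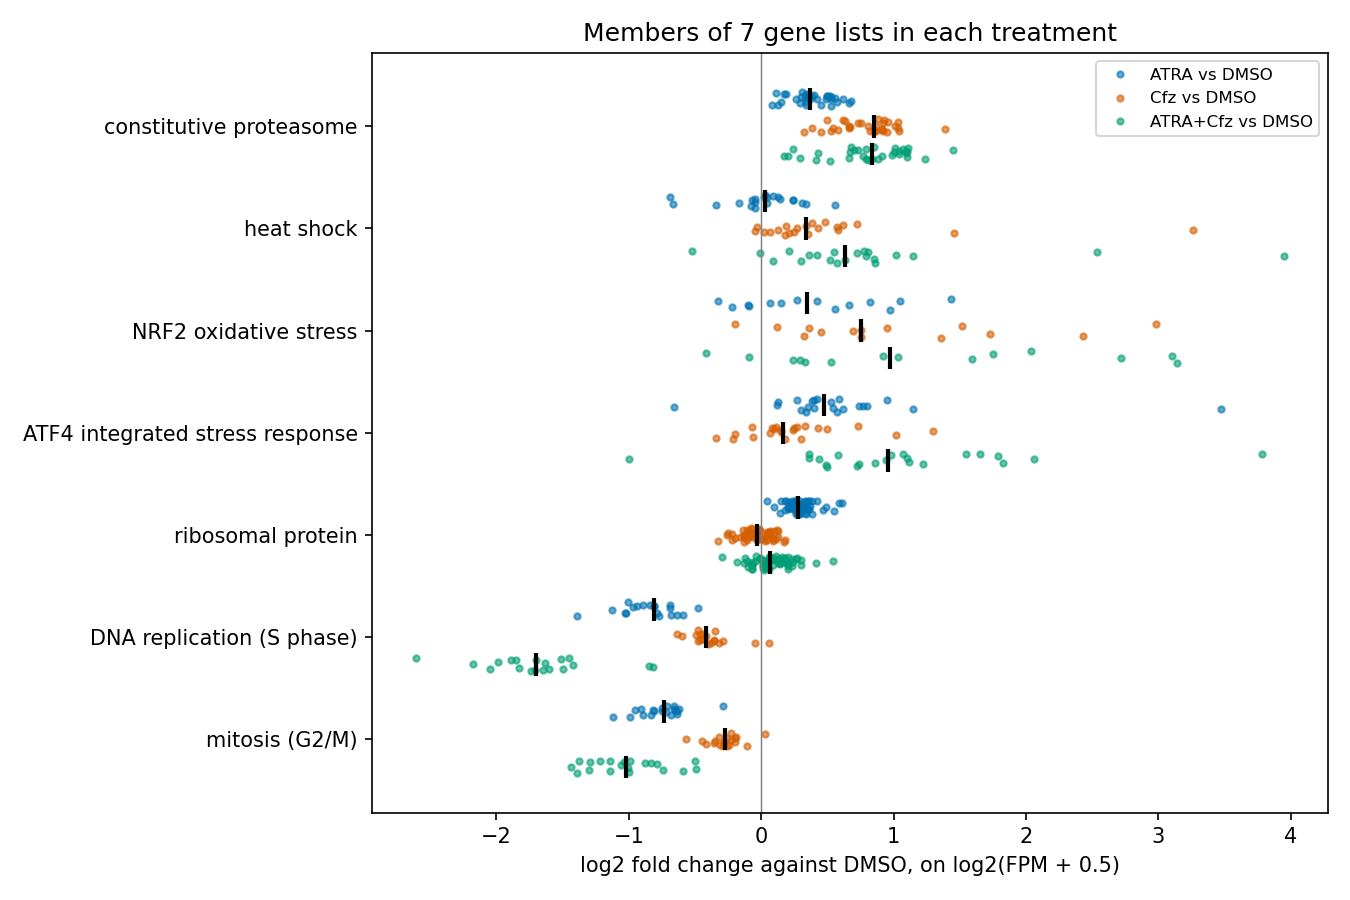
Log2 fold change against DMSO, on log2(FPM + 0.5), of the tested members of 7 gene lists with ATRA, Cfz and ATRA+Cfz; each point is a gene, black bars are list medians and vertical offsets within a list only separate points. The median of the DNA replication list is -0.81 with ATRA, -0.42 with Cfz and -1.7 with ATRA+Cfz, and that of the constitutive proteasome 0.37, 0.85 and 0.84.

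The second comparison asked what a carfilzomib pulse alone left 12 h later, in 1 library, so that no difference here has a replicate check. HMOX1, the heme-degrading enzyme, rose from 20.1 ± 4.4 FPM in 3 DMSO libraries to 159 FPM (2.98 ± 0.18 SE, limma, Benjamini-Hochberg adjusted p = 9.4e-07), and SQSTM1 from 407 ± 6.9 to 1890 FPM (2.22 ± 0.05 SE). The inducible HSP70 genes HSPA1A and HSPA1B are near-identical copies with lanes that differed, so the split between them is uncertain. HSPA1A was called at 6.1 ± 0.5 against 62.7 FPM (3.26 ± 0.27 SE) and HSPA1B at 98.9 ± 19 against 270 FPM (1.46). Their sum went from 105 to 332 FPM, 3.17-fold. All 33 constitutive proteasome genes rose (33 adjusted over the list alone, median 0.85, at percentile 100 of random lists). Among them were PSMC4, an ATPase of the regulatory particle, from 100 ± 3.4 to 263 FPM (1.39), PSMB2 (1.04) and PSMD2 (1.03). The drug's target PSMB5 rose from 29.5 ± 2 to 53.5 FPM (0.85 ± 0.09 SE).

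Other large rises were HSPA6 (2.72), a further HSP70 gene, the interferon-induced IFI44 from 2.11 ± 0.49 to 15.8 FPM (2.66) and OSGIN1 (2.43), an oxidative stress gene. Further rises were PCYT1B (2.15), GABARAPL1 from 13.6 ± 1.7 to 61 FPM (2.14) and the antisense gene HAGLR (2.43), which cannot be told from its partner strand here. The processed pseudogenes CKS1BP3 and HMGN2P5 also passed, at 2.68 and 6.22 FPM with Cfz and 0 and 0.116 FPM with DMSO, and are uncertain. The largest falls included PIK3AP1, a B cell adaptor of phosphoinositide 3-kinase, from 13.9 ± 1.7 to 5.38 FPM (-1.28). They also included YPEL1 (-1.43), FJX1 (-1.23), ACSM3 (-1.18), TXNRD3 (-1.13), B3GAT2 (-1.12, and 0.09 in lane 1 alone) and the antisense gene FOXD1-AS1 (-1.31). UTP14C (-2), ANKRD36BP1 (-1.91, call lost without DMSO 1 at -1.8), RAB43 (-1.44), TMEFF1 (-1.22) and 1 of the gene IDs named HERC3 (-1.36) had lanes that differed beyond sampling noise and are uncertain.

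Heat shock genes were higher with Cfz for 16 of 21 and lower for 0 (16 and 0 adjusted over the list alone, median 0.34, percentile 100), with HSP90AA1 from 1270 ± 13 to 2090 FPM (0.72) and HSPA8 from 2850 ± 38 to 4230 FPM (0.57). NRF2 genes rose for 12 of 14 (13 adjusted over the list alone, median 0.75, percentile 100), with SRXN1 from 65.2 ± 4 to 216 FPM (1.73), the ferritin light chain FTL from 1340 ± 110 to 3430 FPM (1.36) and SLC7A11 (1.52). Ubiquitin and autophagy genes rose for 13 of 15 (13 higher and 1 lower adjusted over the list alone, median 0.66, percentile 100), with UFD1 (1.14), a cofactor of the VCP segregase. ATF4 genes rose for 7 of 22 (10 higher and 1 lower adjusted over the list alone, median 0.17, percentile 99.99), and for 11 with median-ratio scaling. Examples were CTH (1.3) and PPP1R15A (1.02). DNA replication genes fell for 16 of 19 (16 adjusted over the list alone, median -0.42, percentile 0), with MCM4 (-0.46), UHRF1 (-0.64) and the transcription factor E2F1 (-0.6). Mitosis genes fell for 13 of 20 (14 adjusted over the list alone, median -0.27, percentile 0.06), with CDK1 (-0.57) and TOP2A (-0.45). The number was 7 without ATRA 1 or ATRA 2 and 5 with median-ratio scaling.

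In the interferon-stimulated list, 10 of 42 were higher with Cfz and 5 lower (10 and 5 adjusted over the list alone, with 3 lower without any one of the ATRA libraries), with a median of -0.02 and a mean of 0.11. SAMD9L (0.8) and PARP14 (0.76) rose and PLSCR1 (-0.76) fell. OAS1 was at 13.6 FPM (-0.16 ± 0.14 SE, limma, Benjamini-Hochberg adjusted p = 0.46). OAS2 (-0.2) and OAS3 (-0.35) were called at adjusted p = 2.9e-02 and 4.2e-02 in limma with Benjamini-Hochberg adjustment. Both calls were lost without any one of the ATRA libraries, at -0.2 and -0.35, and with median-ratio scaling, at -0.13 and -0.29. The call of OAS2 was also lost without DMSO 2 (-0.18). CYP26A1 fell from 83.2 ± 8.5 to 51.4 FPM (-0.69) and CD38 from 70.6 ± 7.8 to 39 FPM (-0.84 ± 0.09 SE, limma, Benjamini-Hochberg adjusted p = 7.2e-05). RARA (0.15), RARB (0.34), RARG (-0.09) and IRF1 (-0.06) were not called. Ribosomal protein genes had 8 of 59 lower and 0 higher (7 and 0 adjusted over the list alone), but 6 higher and 4 lower with median-ratio scaling and 13 higher and 14 lower without DMSO 3. Mitochondrially encoded genes had 3 of 13 higher (3 adjusted over the list alone), and 13 without DMSO 3. EPCAM, an epithelial surface marker, was the marker of another cell type that rose most with Cfz, from 0.628 ± 0.29 to 3.34 FPM (1.81). The stromal marker PDGFRB, at 0.4 to 0.987 FPM with DMSO and 2.29 FPM with Cfz, rose too (1.24). Neither was called in lane 1 alone or with DESeq2.

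With Cfz, limma called 3948 genes, 1257 higher and 2691 lower, with 162 at least 2-fold higher and 65 at least 2-fold lower. The share of calls that were higher was 31.8%, against 47.8% with median-ratio scaling, 42.2% with edgeR, 53.1% with DESeq2 and 49.3% after correction for GC content and length, so the balance of small changes is not fixed by these data. Each single DMSO or ATRA library was also tested against the rest of its own group. That fit differs from the fit for Cfz, because the tested library was left out of the spread. By far the most calls, 1337, came from DMSO 3, whose deviation was then not in the spread, while the spread for Cfz held it. When another library was tested, DMSO 3 widened the spread, so the few calls there say little.

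With both agents, in 1 library and again with no replicate check, the ATRA genes and the Cfz genes were both far from DMSO. HAPLN3 (5.87), CYP26A1 (5.69 ± 0.08 SE), ABCB1 (5.34), MFGE8 (5.33), SV2B (4.58), TRIM31 (4.51), ACSM5 (4.35), CALCRL (4.3), IRAK2 (4.11) and CPNE5 (3.99, uncertain) rose. So did HSPA6 from 0.264 ± 0.056 to 15.4 FPM (4.38 ± 0.31 SE, limma, Benjamini-Hochberg adjusted p = 3.6e-07). The largest fall was HES6, a basic helix-loop-helix factor, from 26.4 ± 1.1 to 1.13 FPM (-4.05 ± 0.14 SE). Its lanes differed in ATRA 2, which is not part of this comparison, and its reads in ATRA+Cfz were too few for that check. HES6 was followed by ITGB8 (-3.71), SEMA5A (-3.54), CBLN2 (-3.33), ID2 (-3.29), NEURL1 (-3.24) and LOC101927811 (-3.2). Then came ADAMTS15 (-2.98), CX3CR1 (-2.89), RASAL2 (-2.84) and GRIK4 (-2.83), with the pseudogene DHFRP1 (-2.9) uncertain. CD38 stood at 376 FPM (2.41), OAS1 at 115 FPM (2.87), OAS2 at 102 FPM (1.25), OAS3 at 47.1 FPM (1.77), and IRF1 at 229 FPM (1.46), all called higher than DMSO. So were RARA at 88.2 FPM (0.74), RARB at 1.77 FPM (1.49) and PSMB5 at 51.9 FPM (0.81). RARG, at 8.36 FPM, was not called (-0.02).

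All 19 DNA replication genes (median -1.7) and all 20 mitosis genes (median -1.02) fell with ATRA+Cfz against DMSO, and as many when adjusted over the list alone. All 33 proteasome genes rose (33 adjusted over the list alone, median 0.84), and 20 of 22 ATF4 genes rose with 1 lower (20 and 1 adjusted over the list alone, median 0.96). Of 21 heat shock genes, 17 rose and 1 fell (17 and 1 adjusted over the list alone, median 0.63), with 0 lower without DMSO 1. Rises took in 14 of 15 ubiquitin and autophagy genes (14 adjusted over the list alone, median 0.8) and 11 of 14 NRF2 genes with 1 lower (11 and 1 adjusted over the list alone, median 0.98). Among 12 retinoid genes, 9 rose and 1 fell (9 and 1 adjusted over the list alone, median 1.73). Of 6 OAS pathway members, 6 rose (6 adjusted over the list alone). The 42 interferon-stimulated genes went both ways, with a median of -0.02 and a mean of 0.17. That median stood at percentile 74.24 of random lists, so it lay among theirs. Against DMSO, limma called 8002 genes, 3173 higher and 4829 lower, with 657 at least 2-fold higher and 1266 at least 2-fold lower. The share of calls that were higher was 39.7%, against 49.3% after correction for GC content and length.

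The ATRA effect after a Cfz pulse was read from 1 library against 1, ATRA+Cfz against Cfz, with the spread taken from the DMSO and ATRA libraries and no replicate check. HAPLN3 (6.42 ± 0.18 SE), CYP26A1 (6.38 ± 0.1 SE, limma, Benjamini-Hochberg adjusted p = 7.9e-12), MFGE8 (5.59), ABCB1 (5.13), SV2B (4.55) and TRIM31 (4.38) rose, and ITGB8 (-3.3), CX3CR1 (-3.01), LOC101927811 (-2.94), HES6 (-2.94, uncertain), NEURL1 (-2.91) and ID2 (-2.83) fell. CD38 rose from 39 to 376 FPM (3.25), OAS1 from 13.6 to 115 FPM (3.03), OAS2 from 37.2 to 102 FPM (1.44), OAS3 from 10.4 to 47.1 FPM (2.12), IRF1 (1.52), RARA (0.59) and RARB (1.15, lost with a pseudocount of 0.1 at 1.58). PSMB5 differed by -0.04 ± 0.11 (SE) and was not called.

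DNA replication genes fell for 18 of 19 (18 adjusted over the list alone, median -1.36) and mitosis genes for 19 of 20 (19 adjusted over the list alone, median -0.79) when ATRA followed Cfz. ATF4 genes rose for 17 of 22 with 1 lower (18 and 1 adjusted over the list alone, median 0.7), and heat shock genes for 12 of 21 (13 higher and 1 lower adjusted over the list alone, median 0.25). Retinoid genes rose for 9 of 12 with 1 lower (9 and 1 adjusted over the list alone, median 1.4), and 0 were lower without ATRA 1. Ubiquitin and autophagy genes rose for 9 of 15 (12 higher and 1 lower adjusted over the list alone, median 0.36). Of 33 proteasome genes, 4 rose and 3 fell (3 and 3 adjusted over the list alone, median 0.02). Without DMSO 3, 9 rose, and without ATRA 2, 1 fell. Here limma called 4818 genes, 2028 higher and 2790 lower, with 400 at least 2-fold higher and 606 at least 2-fold lower.

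Across the 15827 genes, the log2 fold changes of ATRA without and after Cfz, which share no library, had a Pearson r of 0.778, a Spearman rho of 0.687 and a slope of 0.88. Genes are not independent replicates, so no p is given. Of the 7704 genes called with ATRA alone, 89.3% had the same direction after Cfz. Both comparisons called 1535 genes higher, where independent lists would share 431.6. Both called 2408 lower, where they would share 764.4, and 62 genes were called in opposite directions. The Cfz effect without and with ATRA had an r of 0.571, a rho of 0.543 and a slope of 0.63. There were 844 genes higher in both (133.5 by chance), 1676 lower in both (544.6 by chance) and 37 opposite.

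**Figure D3:**
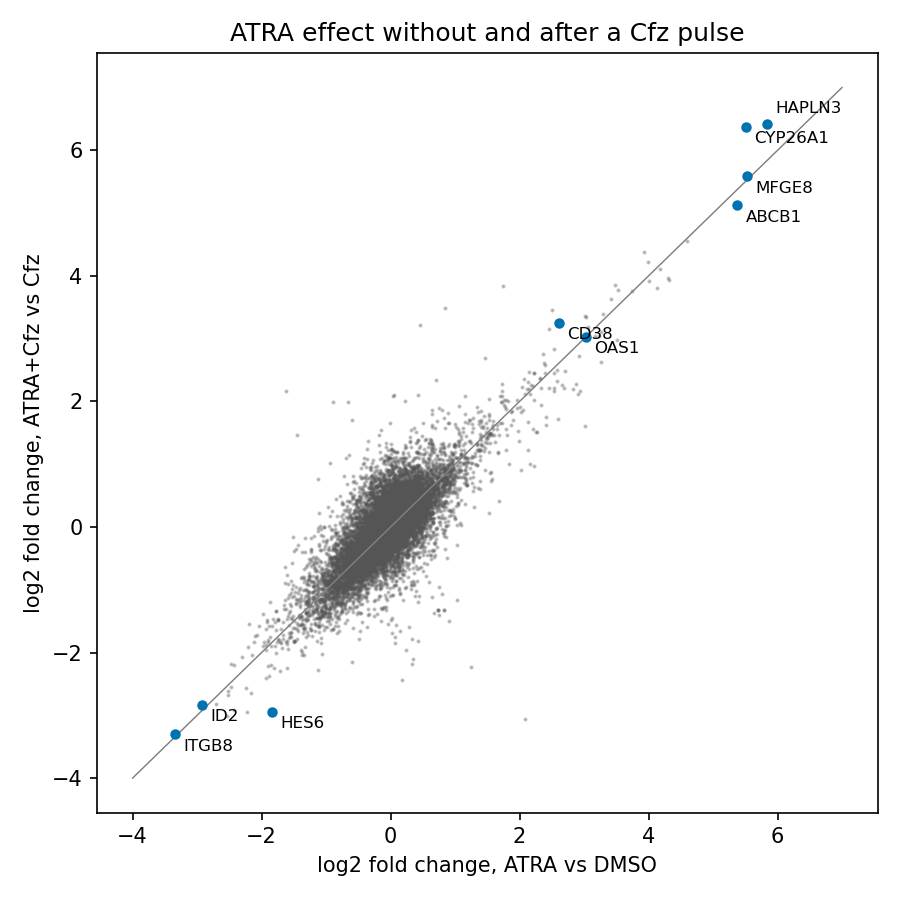
Log2 fold change of each of 15827 genes with ATRA in cells pulsed with vehicle (x axis, 3 libraries against 3) and with carfilzomib (y axis, 1 library against 1), both on log2(FPM + 0.5); the line marks equal values and 9 named genes are drawn larger. Pearson r is 0.778.

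The Cfz effect in cells that then received ATRA was read from ATRA+Cfz (n = 1) against ATRA (n = 3). HMOX1 rose from 18.4 ± 0.78 to 177 FPM (3.23 ± 0.18 SE, limma, Benjamini-Hochberg adjusted p = 1.4e-06). SQSTM1 rose from 748 ± 7 to 3210 FPM (2.1), SLC7A11 from 35.9 ± 1.4 to 115 FPM (1.67) and HSPA6 from 0.948 ± 0.44 to 15.4 FPM (3.49). The summed level of HSPA1A (4.62) and HSPA1B (2.71), uncertain one by one, went from 90.8 to 674 FPM, 7.42-fold. IMPA2, an inositol monophosphatase, fell from 11.1 ± 0.44 to 3.32 FPM (-1.6 ± 0.12 SE) and HES6 from 7.03 ± 0.72 to 1.13 FPM (-2.2, uncertain).

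RN7SL1 (2.41), a signal recognition particle RNA with many copies, rose. MT-TS1 (-2.64), a mitochondrial tRNA, 1 of the gene IDs named RN7SK (-1.81), DHFRP1 (-2.11) and 1 of those named HERC3 (-2.04) fell. Copies or differing lanes make these 5 genes uncertain, as they do the pseudogene HMGN2P5, at 3.9 FPM against 0 in all 3 ATRA libraries. OAS2 fell by 0.25 on the log2 scale, a call lost with DESeq2 (-0.22), and IRF1 rose by 0.19, a call lost without ATRA 3 (0.17). CYP26A1 (0.18), CD38 (-0.2), PSMB5 (0.19), OAS1 (-0.16), OAS3 (-0.32), RARA (0.01), RARB (0.53) and RARG (-0.28) were not called.

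DNA replication genes fell for 18 of 19 (18 adjusted over the list alone, median -0.88), with MCM5 from 95 ± 0.7 to 44.2 FPM (-1.1), MCM2 from 155 ± 1.5 to 76.9 FPM (-1.01) and E2F1 from 40.2 ± 1.8 to 15.3 FPM (-1.37). Proteasome genes rose for 26 of 33 (28 adjusted over the list alone, median 0.47), with PSMC4 (0.91) and PSMD12 (0.74). Heat shock genes rose for 18 of 21 with 1 lower (18 and 1 adjusted over the list alone, median 0.38), and 0 were lower without any one of the ATRA libraries. Examples were HSP90AA1 from 1220 ± 7.9 to 2800 FPM (1.2) and DNAJB1 (0.91). NRF2 genes rose for 11 of 14 (12 higher and 1 lower adjusted over the list alone, median 0.59), and ubiquitin and autophagy genes for 13 of 15 (13 higher and 1 lower adjusted over the list alone, median 0.54). ATF4 genes rose for 15 of 22 (15 adjusted over the list alone, median 0.36), with DDIT3 (1.22) and PPP1R15A (0.99). Cholesterol synthesis genes fell for 14 of 23 (15 adjusted over the list alone, median -0.27), with PMVK (-0.79) and EBP (-0.67). Ribosomal protein genes fell for 36 of 59 (43 adjusted over the list alone, median -0.21).

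Mitochondrially encoded genes rose for 11 of 13 with ATRA+Cfz against ATRA (12 adjusted over the list alone, median 0.76), and for 3 with robust empirical Bayes, with MT-ND1 from 2290 ± 83 to 4150 FPM (0.86), a call lost with robust empirical Bayes at the same value. MHC class I genes fell for 8 of 12 with 1 higher (9 and 1 adjusted over the list alone). The number lower was 4 without ATRA 2 and 3 after correction for GC content and length. Immunoproteasome genes fell for 4 of 5 (5 adjusted over the list alone). Mitosis genes fell for 9 of 20 with 1 higher (11 and 1 adjusted over the list alone). There were 16 lower without DMSO 3, and 0 higher without DMSO 2 or any one of the ATRA libraries. Here limma called 4884 genes, 1681 higher and 3203 lower, with 146 at least 2-fold higher and 138 at least 2-fold lower. The share of calls that were higher was 34.4%, against 45.3% with edgeR.

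The interaction tests whether the effect of ATRA differed after Cfz. It is positive where ATRA+Cfz lay above the sum of the separate log2 effects and rests on 1 library in each of 2 groups. MCM5, a subunit of the replicative helicase, was below the sum, at 176 ± 1.6, 95 ± 0.7, 138 and 44.2 FPM with DMSO, ATRA, Cfz and ATRA+Cfz (-0.74 ± 0.07 SE, limma, Benjamini-Hochberg adjusted p = 2.3e-03), as were MCM2 (-0.61) and E2F1 (-0.76). PSMB4 was at 286 ± 4.7, 424 ± 3.7, 475 and 487 FPM in the same order (-0.53 ± 0.06 SE), and PSMB5 (-0.66), PSMB6 (-0.54) and PSMC4 (-0.48) were below the sum too. HSPA1B (1.25, uncertain), DNAJB1 (0.57), HSP90AA1 (0.48) and HSPA4L (0.36) lay above the sum. So did CYP26A1 (0.86), CD38 (0.64) and UBD, a ubiquitin-like modifier, at 0.2 ± 0.14, 1.81 ± 0.13, 0.131 and 8.56 FPM (2.11 ± 0.39 SE). In the same order, CYP26A1 was at 77.7 to 92.9, 3810 to 3820, 51.4 and 4320 FPM, and CD38 at 64.7 to 79.5, 426 to 434, 39 and 376 FPM. CYP26A1 and CD38 were thus lower with Cfz than with DMSO, and CD38 was lower with ATRA+Cfz than with ATRA. Of the 31 genes named by rule and called in the interaction, 1, 4 and 10 were called without ATRA 1, ATRA 2 and ATRA 3, and 24, 21 and 31 without DMSO 1, DMSO 2 and DMSO 3. Only MCM5 was called with each DMSO or ATRA library left out in turn. The lone Cfz and ATRA+Cfz libraries, on which the interaction rests, cannot be left out.

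Of 33 proteasome genes, 20 were below the sum and 0 above (32 and 0 adjusted over the list alone, median -0.38), and the fitted value was below 0 for all 33. DNA replication had 12 of 19 below (17 adjusted over the list alone, median -0.42), and heat shock 4 of 21 above (10 adjusted over the list alone, median 0.21). Without ATRA 1, ATRA 2 and ATRA 3 in turn, the called proteasome genes numbered 0, 0 and 2, the replication genes 1, 3 and 5 and the heat shock genes 0, 0 and 1, with medians of -0.37 to -0.39, -0.42 to -0.43 and 0.14 to 0.3. Without DMSO 3 these 3 lists had 32, 16 and 9. NRF2 genes had 2 of 14 below (6 adjusted over the list alone, median -0.26), and ubiquitin and autophagy genes 1 of 15 (4 adjusted over the list alone, median -0.11). In either list 0 genes were called below the sum without any one of the ATRA libraries. Without DMSO 3, 6 and 4 were called below it and 1 and 2 above. RARA (-0.14), RARB (0.19), RARG (-0.19), OAS1 (0.01), OAS2 (-0.05), OAS3 (0.04) and IRF1 (0.25) were not called.

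For the interaction, limma called 364 genes, 157 above and 207 below the sum, with 11 and 17 at least 2-fold from it, and 2858 genes had an unadjusted p under 0.05. The count was 2, 8 and 35 without ATRA 1, ATRA 2 and ATRA 3, 240 and 164 without DMSO 1 and DMSO 2, and 1985 without DMSO 3. The share of calls above the sum was 43.1%, against 22.6% with median-ratio scaling, 24% with DESeq2 and 21% after correction for GC content and length.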

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

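The correlation over called genes, the heat shock test and the test of the Cfz library against the ATRA+Cfz library were chosen only after the results were seen. The correction for GC content and length and the counts of list members under other settings were chosen after the data were seen. The interaction results here were picked out because the ATRA effect after Cfz differed from the ATRA effect without it. The genes called with Cfz and the splits of the DMSO and ATRA libraries are weighed beside them. No pattern below has a replicate of the Cfz or the ATRA+Cfz library.

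The interaction called 364 genes in limma, and 20 of 33 constitutive proteasome genes were called below the sum of the separate effects. In DNA replication 12 genes were called below it, and in heat shock 4 genes above it. Without ATRA 1, ATRA 2 and ATRA 3 the 364 became 2, 8 and 35, and without DMSO 3 1985. In the same order of ATRA libraries the proteasome genes called became 0, 0 and 2, the replication genes 1, 3 and 5 and the heat shock genes 0, 0 and 1.

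The first pattern is the number of genes called with Cfz, 3948 from 1 library. A technical difference of the kind that sets DMSO 3 apart stays open for the Cfz library. The DMSO 3 difference did not correlate across genes with the Cfz effect measured in ATRA+Cfz against ATRA (r = 0.044, and -0.034 over the genes called with Cfz). That comparison does not hold the Cfz library, so it argues against such a difference as the whole cause for the ATRA+Cfz library alone. As part of the cause it stays open there too. The third principal component (5.8% of the variance) placed DMSO 3 (-15.3) and ATRA+Cfz (-13.9) opposite Cfz (17), with the other libraries at -2 to 6.6. Whether the DMSO 3 difference goes with the interaction was not tested. Another trait goes with such a difference: mitochondrially encoded genes took 5.85% of reads in DMSO 3, 5.43% with Cfz and 5.72% with ATRA+Cfz, against 4.12% and 4.09% in DMSO 1 and DMSO 2. For those genes it stays open in both libraries that received Cfz. Trends on GC content and transcript length are argued against as the whole cause, because 3587 genes were called after their removal, against 1337 for the lone DMSO library that stood farthest from its group. The count for that DMSO library was not itself corrected for these trends, and its spread left the library out. Across genes, Cfz against DMSO followed these trends little (r = -0.045 with GC content and -0.069 with log length). ATRA+Cfz against ATRA followed GC content more (r = -0.248), so this test covers the Cfz library and not the ATRA+Cfz library. A deviation confined to the Cfz library is argued against as the whole cause, because 91% of the genes called with Cfz had the same direction in ATRA+Cfz against ATRA, a comparison that shares no library with this one. There 844 genes were called higher in both and 1676 lower in both, where independent lists would share 133.5 and 544.6. It stays open for part of the calls, as does a difference in handling shared by both libraries that received Cfz. An effect of carfilzomib, which the design names, stays open beside these and may account for part or all of the calls.

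The second pattern is the constitutive proteasome list, with a median interaction of -0.38 and all 33 fitted values below 0. A uniformly weaker Cfz response in the ATRA+Cfz library is argued against as the whole cause. The reason is that the heat shock list lay above the sum, with a median of 0.21 (95% bootstrap interval 0.08 to 0.35). That median was 0.14 after correction for GC content and length and 0.14 with a pseudocount of 2, with no interval computed. Other results go with a weaker response. Across all genes, the slope of the Cfz effect with ATRA on that without it was 0.63. The median interaction was -0.26 for the NRF2 list and -0.11 for the ubiquitin and autophagy list, which rose with Cfz too. A weaker response of part of the genes therefore stays open. Trends on GC content and length are argued against for this list, because the median was -0.4 after their removal (95% bootstrap interval -0.43 to -0.33). Across all genes the interaction had an r of -0.236 with GC content and 0.12 with log length. For the other genes called in the interaction these trends therefore stay open. Both bootstrap intervals resample genes and cover neither the 1 library nor the correlation of genes. A candidate explanation is a ceiling, since ATRA alone and Cfz alone both raised these genes, but it was not tested and a deviation of the lone libraries stays open.

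For ATRA against DMSO, 1 of the 10 splits of the 6 libraries into 3 and 3, the real one, gave as many as 7704 called genes, and the highest other split gave 0 in limma. In the other splits 148 to 249 genes had an unadjusted p under 0.05. With 10 splits no share under 0.05 can be reached. Every other split also mixes DMSO and ATRA libraries in both groups, so the ATRA effect widens the spread there. The 0 calls of those splits therefore cannot be weighed against the 7704.

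The genes named by rule and called in the interaction follow, each as the log2 interaction. In DNA replication, MCM5 was at -0.74 ± 0.07 (SE), MCM2 at -0.61 and E2F1 at -0.76. In the proteasome, PSMB5 was at -0.66, PSMB4 at -0.53, PSMB6 at -0.54 and PSMC4 at -0.48. In heat shock, HSPA1B was at 1.25 (uncertain, with differing lanes and a near-identical copy), DNAJB1 at 0.57, HSP90AA1 at 0.48 and HSPA4L at 0.36. The redox genes TXN and SRXN1 were at -0.41 and -0.51, and the autophagy gene GABARAPL1 at -0.82. ALDH1L2 and PSAT1, of the ATF4 list, were at 0.71 and 0.41. The retinoid genes CYP26A1 and CD38 were at 0.86 and 0.64, the interferon-stimulated SAMD9 at 0.53 and the plasma cell gene MZB1 at -0.36. CYP26A1 and CD38 were lower with Cfz alone than with DMSO, which raises their interaction. UBD was at 2.11 and LOC150051 at -1.56. Lanes that differed or near-identical copies make HES6 (-1.1), ANKRD36BP1 (3.78), RN7SL1 (2.05), MT-TS1 (-2.19), RN7SK (-1.72), CHKB-CPT1B (1.3), SMG1P1 (1.23), SULT1A4 (-1.25) and HLA-DRB5 (-1.25) uncertain.

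The limma Benjamini-Hochberg adjusted p of these genes ran from 2.3e-03 for MCM5 to 4.9e-02 for HSPA4L. Leaving out 1 DMSO or ATRA library at a time moved their values by a median of 0.01 to 0.03 and by at most 0.65, for ANKRD36BP1 without ATRA 2. Without ATRA 1 only MCM5 was still called, without ATRA 2 MCM5, MCM2, E2F1 and ANKRD36BP1 were, and without ATRA 3 10 of the 31 were. Without DMSO 1, DMSO 2 and DMSO 3, 24, 21 and 31 of the 31 were called.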

How the results depend on the processing

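The correction for GC content and length was chosen after the data were seen. So were the list tests with 1 library left out and the agreement with edgeR and DESeq2. Over 270 pairs of a named gene and a comparison, 4695 of 4952 values under other settings kept their direction and side of the threshold, 203 were weaker, 28 stronger and 26 reversed. Of the weaker values 43 came from lane 1 alone, which holds fewer reads, and 33, 29 and 24 from leaving out ATRA 1, ATRA 2 and ATRA 3. Rescaling each library moved nothing, since the libraries already shared 1 total. Depth limits low genes, since 3 reads are 0.175 to 0.212 FPM.

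In the order ATRA, Cfz and ATRA+Cfz against DMSO, ATRA+Cfz against Cfz and against ATRA, and interaction, lane 1 alone called 4860, 1421, 5115, 2280, 2164 and 17 genes, and an added 2-fold minimum 785, 227, 1923, 1006, 284 and 28. DESeq2 called 2013 genes with Cfz, 3108 for ATRA+Cfz against Cfz and 2905 against ATRA. The interaction had 548 calls with a minimum of 5 FPM, where fewer genes were tested, and 2497 with lanes as samples, which overstates n. Leaving out 1 library gave 6678 to 8226, 3319 to 5442, 7440 to 8788, 4297 to 6275, 3903 to 6389 and 2 to 1985 genes in the same order. The list tests for ATRA numbered 13, 12 to 14 with 1 library left out, and 2 with an estimated correlation. For the agreement of the ATRA effect, r was 0.778, and 0.728 and 0.833 with pseudocounts of 0.1 and 2, 0.69 with no filter, 0.881 with a minimum of 5 FPM, 0.546 in lane 1 alone, 0.704 with edgeR, 0.705 with DESeq2 and 0.763 to 0.775 with 1 library left out. Where no cause is given, the cause was not tested.

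Reversed values in lane 1 alone were, with Cfz, UTP14C 1.33, HERC3 2.75, B3GAT2 0.09 and OAS1 0.06. Others in lane 1 were RARG with ATRA -0.09 and for ATRA+Cfz against Cfz -0.33, PSMB5 for the latter 0.12, and the interaction of SULT1A4 0.62, RARB -0.17 and OAS1 -0.1. Of these, UTP14C, HERC3, B3GAT2 and SULT1A4 had been called. With Cfz, RARG was 0.02 after the GC correction, and IRF1 0.01 with median-ratio scaling and 0 after the GC correction. For ATRA+Cfz against DMSO, RARG was 0.03 with median-ratio scaling, 0.27 after the GC correction, 0.05 with edgeR, 0.04 with DESeq2 and -0.08 to 0.04 with 1 library left out. In the interaction, RARB was -0.02 with edgeR. OAS1 there was 0 with a pseudocount of 2, -0.04 with median-ratio scaling, 0 with DESeq2 and -0.15 to 0.09 with 1 library left out. OAS3 was -0.01 with median-ratio scaling and -0.06 to 0.11 with 1 library left out. The cause was not tested.

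Replicate numbers are shared by DMSO and ATRA, but the correlations of deviations of same-numbered libraries were -0.006, -0.002 and 0.006, so they were not read as pairs. With the number as a block, 7661 genes were called with ATRA (7449 of them among the 7704) and 12 lists.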

Other observations

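The neighbour test was chosen only after HAPLN3 and MFGE8 had been seen to lie side by side, and its splits by strand, name and direction and the genes of the next paragraph were chosen after the results were seen.

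Further genes outside the rule rose with ATRA. The phosphatase gene DUSP5, which acts on ERK kinases, rose from 319.7 ± 22.8 to 1495 ± 23.5 FPM (SD, n = 3 each, log2 fold change 2.23). SLC25A20, the mitochondrial carnitine carrier, rose from 96.5 ± 6.11 to 479.5 ± 4.86 FPM (2.31), and SREBF1, a transcription factor of lipid synthesis, from 21.2 ± 3.28 to 113 ± 4.55 FPM (2.39). The ligands of the checkpoint receptor PD-1, CD274 and PDCD1LG2, rose from 2.51 ± 0.54 to 6.57 ± 0.28 FPM (1.25) and from 3.43 ± 0.51 to 8.32 ± 0.83 FPM (1.17). The integrin subunit ITGB7 was the most abundant gene in the 3 ATRA libraries and in DMSO 1.

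HAPLN3 and MFGE8, among the largest rises named with ATRA, are neighbours in the genome order of tested genes. One hypothesis is that rises with ATRA spread to neighbouring genes. Among 309 genes at least 2-fold higher with ATRA and placed in that order, 33 pairs stood next to each other with overlapping genes left out. Random draws of as many genes from the 15557 placed gave a mean of 4.66 pairs against an upper bound of 9 set for the test (permutation p = 0.0001, the smallest that 10000 draws can give), and draws matched on expression level a mean of 4.6. The pairs include OAS1, OAS3 and OAS2, CDKN1A and CPNE5, CD274 and PDCD1LG2, and SREBF1 and TOM1L2.

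Of the 33 pairs, 15 lay on opposite strands (mean of 2.24 by chance) and 26 had names that do not start alike (4.42 by chance), so families of like-named copies do not account for all pairs. Reads running on from one gene into the next stay open, since the strand setting is unknown and such reads may then be counted for a gene on either strand. Genes at least 2-fold lower with ATRA also stood side by side, with 32 pairs among 472 genes against 10.94 by chance (permutation p = 1e-04, the smallest the draws can give). Genes at least 2-fold higher with Cfz had 2 pairs among 158 genes against 1.23 (permutation p = 0.4). The clustering is therefore not specific to rises, and shared regulation of gene neighbourhoods that already existed before ATRA may give it as well as a spread of the response.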
